A study of Homo sapiens with 104 samples.

How the data were processed

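Gene expression was measured in human bronchoalveolar lavage cells on 104 Agilent whole-genome expression arrays in 1 colour (Cy3), with 31 control samples, 43 samples labelled not SA and 30 labelled SA. Per the labels' protocols, the lavage fluid was spun down, the cells were stored in Trizol, RNA was extracted on an automated system, and RNA integrity was measured on a Bioanalyzer and used to filter samples. The same text also describes brushing of the bronchial epithelium. Agilent Feature Extraction 10.7.3.1 is named in the submitters' processing notes.

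The scanner output deposited by the authors holds intensity values on a linear scale, and per the file headers its processed signal is the spot brightness after background treatment by Feature Extraction. The authors' value table holds log2 values: set against the log2 scanner signal of the same array, its columns had a median slope of 0.999. How the authors normalized that table is not given in the sources used here. Relative to quantile-normalized scanner values it carried a shift between scan rounds that differed from probe to probe, with an SD over probes of 0.234. Within the earlier and later rounds the SD over arrays had a median over probes of 0.0844 and 0.107, which is another measure of spread. The direction of the table's values is settled by the slope, but their centring stays unknown. No column of sample values was left unmatched (0).

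The labels name a later version of the array than the files, which list 45015 spots and 41000 probes other than controls in 2 versions of the design, 70 arrays of the later and 34 of the earlier version. Probes were named through the transcript accession in the files, matched without its version to RefSeq annotation of assembly GRCh38.p14. A total of 26385 probes matched 17780 genes. No coordinates are given, because the files name no genome build for their probes. The 66 probes for Y-linked genes, XIST and TSIX were left out of every test for the donors' privacy.

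Log2 of the processed signal minus the 75th percentile of each array over probes other than controls was the measure in all comparisons. Spots marked as outliers were left out, spots of 1 probe were averaged, probes well above background on at least 30 arrays were kept, and each gene was taken at its probe with the highest mean, which left 14683 genes. The precision is limited by the number of arrays. A pair of not SA files held identical values and was counted as 1 sample, so 103 arrays entered the model (31 control, 42 not SA, 30 SA). Differences between groups were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, all 3 groups in 1 model, 2-sided) with Benjamini-Hochberg adjustment and a threshold of 0.05. The R packages data.table (1.17.8) and jsonlite (2.0.0) were used for reading and joining, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

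A total of 32 gene lists were fixed before the data were examined, as were the tests, the rule for named genes and all alternatives not said to be added. They cover the cell types a lavage can hold (eosinophil, mast cell and basophil, neutrophil, T cell, cytotoxic and NK cell, B and plasma cell, alveolar macrophage, monocyte and recruited macrophage, dendritic cell, ciliated, secretory, basal and squamous and alveolar type II epithelium, erythrocyte). They also cover inflammatory programmes (type 2 inflammation, type I interferon, interferon gamma, IL-17 and neutrophil chemoattractants, NF-kB early response), drug and signalling responses (glucocorticoid-induced genes, cAMP and CREB response genes), asthma susceptibility locus genes and MHC class II. The remaining lists hold eicosanoid, matrix remodelling, cholesterol synthesis, LXR target, NRF2 antioxidant, proliferation, heat shock, cytosolic ribosomal protein and mitochondrial respiratory chain genes. Lists were tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over the 32 lists. The estimated correlation was an alternative fixed beforehand, and a permutation test of the list means (100000 draws of the group labels, 2-sided) was added after the data were seen.

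Genes were named by a fixed rule: in each comparison the 12 largest rises and the 12 largest falls among genes past the threshold with a gene symbol, the called members of each list with the smallest p (at most 4), and in a list not called its members of highest mean signal. FKBP5, TSC22D3, ALOX15, CLC, IL1RL1, IL33, TSLP, GSDMB, ORMDL3, IFNG, SCGB1A1, KRT19, CD3D, FABP4 and CPA3 were named whatever their p. IL1RL1 was not among the genes tested, and 2 genes that the rule names are not reported here.

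Each scanner file was set against every column of the authors' table by correlation. For 8 files the best match was another sample's column, among them the identical file. The other 7 stayed in the model, which had been fixed, and every count was repeated without them as an added alternative (96 arrays, 28 control, 40 not SA, 28 SA). Slide and scan date were taken from the file headers as batches. The alternatives fixed beforehand were quantile normalization, normexp background correction of the median foreground signal (the mean signal was not used here), median scaling, other filters and rules for several probes, another variance model, array weights, only the 2 groups compared, the authors' table, blocks for date, slide and replicate number, covariates for array brightness, epithelial and lymphocyte content, and 2 treatments of 1 SA sample whose labels conflict. Added alternatives left out mismatched arrays, alone or with a block or covariate, or used 1 scan round. The model was tested on simulated data for 14683 genes. Of genes changed by 0.5, 1 and 2 on the log2 scale it recovered 59.7%, 83.6% and 97.0% for SA against control, 59.7%, 88.1% and 97.0% for SA against not SA, and 68.7%, 85.1% and 100% for not SA against control. It called 6, 6 and 9 unchanged genes in those comparisons. The simulated genes were drawn independently, with no scan date effect or mismatched arrays, so these figures need not hold for the real arrays.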

Results

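Gene expression was profiled in cells recovered by bronchoalveolar lavage, a wash of the distal airways whose cells are mostly alveolar macrophages, with lymphocytes, granulocytes and shed epithelium. The series carries asthma in its title, and its samples fell into 31 controls, 43 labelled not SA and 30 labelled SA, which is read here as severe asthma although the labels do not spell it out. Titles of the not SA samples also hold the word control, which those of the SA samples lack. What not SA stands for is not spelled out either, and it was kept as a group apart from the controls. The labels number the samples of each group as biological replicates without saying more about their origin, so p-values measure the spread between these samples. The median share of probes well above background was 73.7% in control, 73.0% in not SA and 71.3% in SA. A pair of not SA scanner files held identical values and was counted as 1 sample.

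Another 7 scanner files did not match their own sample in the authors' table of values. Of these, 2 files of different groups matched each other's column and 5 matched no column, 2 of them labelled control, 2 not SA and 1 SA. The 5 arrays had a median of 9.52 for SCGB1A1, the secretoglobin of club cells, against 2.87 in the other arrays, and of 8.12 for KRT19, an epithelial keratin, against 1.10. FABP4, a marker of alveolar macrophages, had a median of -4.37 in the 5 arrays against 3.08 in the others (log2, relative to the 75th percentile of each array), and CD3D, a T cell receptor component, -0.98 against 0.01. All 7 arrays stayed in the comparisons as designed, and each leading count is also given without them. The arrays were scanned on 12 dates, of which 10 held over 1 group, and on 61 slides. Scan date accounted for a median of 25.5% of the variance of a gene over the 96 matching arrays, against 11.1% with dates shuffled, and group for 4.42%.

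SA samples were compared with controls to ask which genes of lavage cells differ in severe disease. SH3PXD2B, a podosome scaffold protein, rose 2.25-fold in SA (log2 difference 1.17 ± 0.22 SE, adjusted p = 0.00132, limma, n = 30 and 31). GADD45B, a stress-inducible gene, rose by 0.58 ± 0.12 (adjusted p = 0.00535) and CDC42EP3, an effector of the GTPase CDC42, by 0.62 ± 0.12 (adjusted p = 0.00177). Other genes were lower in SA: CREM, a cAMP-responsive transcription factor, fell by 1.25 ± 0.25, the nuclear receptor NR4A2 fell by 1.12 ± 0.25, and the AP-1 subunit FOSL2 fell by 0.98 ± 0.16 (adjusted p = 0.00243, 0.0124 and 0.000150). VEGFA, the vascular growth factor, fell by 1.29 ± 0.25 (adjusted p = 0.00177). The immediate-early genes FOS and JUN differed by 0.20 ± 0.28 and 0.13 ± 0.16 without passing.

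In all, 56 of 14683 genes passed the threshold between SA and control, 13 higher and 43 lower in SA. The rises also included CD180, a toll-like receptor homologue of the B cell and macrophage surface (1.09), the growth factor PDGFB (0.88), PRR4 (0.82), the ribosomal protein RPS26 (0.64), RASGEF1B (0.55), KLF9, a glucocorticoid-inducible transcription factor (0.51), the histone demethylase KDM3A (0.30) and IRF1, a transcription factor of the interferon gamma response (0.29). The falls also included the adhesion molecule CXADR (-1.42), SYT4 (-1.39), ZNF331 (-1.35), ERRFI1, a feedback inhibitor of the EGF receptor (-1.15), the kinase PLK2 (-1.14), RPH3A (-1.14), IFRD1 (-1.13) and RND3 (-1.02). RPH3A was well above background on 14 of 31 control and 4 of 30 SA arrays. The probes of PRR4, RPS26 and CREM differed in size, from 0.01 to 0.82, from 0.26 to 0.73 and from -1.59 to -0.19. Without the 7 mismatched arrays 426 genes passed (128 higher, 298 lower), among them all 56, and with the values of the authors 318 passed (128 higher, 190 lower). With the scan date as a block 6 passed over all arrays, and 93 (17 higher, 76 lower) without the 7, among them CREM (-1.09, adjusted p = 0.0400) and FOSL2 (-0.78, adjusted p = 0.0262) but neither NR4A2 (-0.70, adjusted p = 0.433) nor SH3PXD2B (0.95, adjusted p = 0.0990). Within the 5 scan dates that held both groups, SH3PXD2B and CDC42EP3 were higher in SA on 5, VEGFA lower on 5, and CREM, NR4A2 and FOSL2 lower on 4. With the 7 left out, these dates held 12 of 28 SA and 23 of 28 control arrays. The genes were picked in the same arrays, so these counts are no independent test of scan date.

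**Figure D1:**
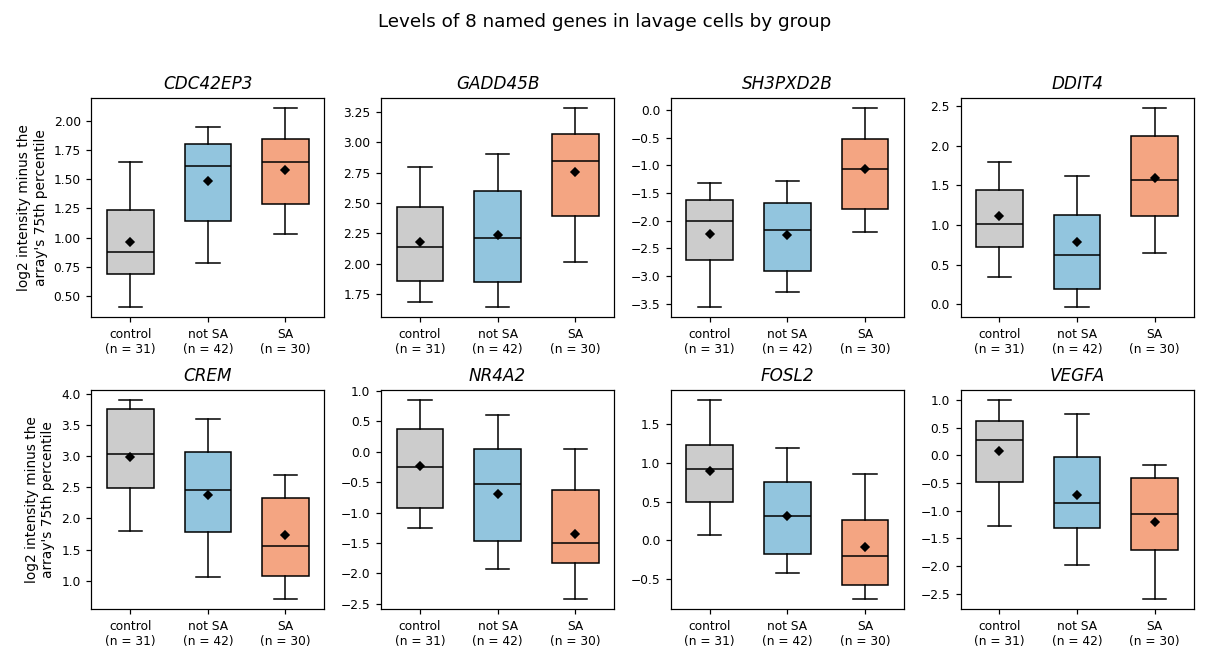
Levels of 8 named genes by group (vertical axis: log2 intensity minus the 75th percentile of the array; n = 31 control, 42 not SA and 30 SA). Boxes span the quartiles with a line at the median, diamonds mark the mean, and whiskers reach the 10th and 90th percentiles; mean CREM was 2.98, 2.38 and 1.74 from control through not SA to SA.

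Of the gene lists, cAMP and CREB response genes were lower in SA than in control, by a mean of -0.49 ± 0.15 (SE; camera adjusted p = 7.18e-07; adjusted p = 0.170 with an estimated correlation). Of its 18 measured members 3 fell (CREM, NR4A2 and FOSL2), 1 rose and 14 did not pass over all genes; adjusted over the list alone, 9 were lower and 1 higher. SIK1, a kinase on the list, had probes between -1.55 and 0.15. Permuting the group labels over the list mean gave an adjusted p of 0.0307, and 0.00256 without the 7 arrays. The difference was -0.34 ± 0.16 with the scan date as a block and without the 7 arrays, and the list was lower in SA on 4 of the 5 dates with both groups. Glucocorticoid-induced genes were higher, by 0.30 ± 0.09 (camera adjusted p = 2.95e-05; adjusted p = 0.130 with an estimated correlation; permutation adjusted p = 0.0717, and 0.0126 without the 7 arrays). Among 18 measured members KLF9 rose and 17 did not pass; adjusted over the list alone 6 were higher. FKBP5 and TSC22D3, classical glucocorticoid targets, differed by 0.40 ± 0.19 and 0.46 ± 0.17 without passing (adjusted p = 0.604 and 0.355). With the block and without the 7 arrays the list difference was 0.29 ± 0.09, higher on 4 of the 5 dates.

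Camera called 7 lists between SA and control, 4 higher and 3 lower, and none (0) with an estimated correlation, where 3 lists had an unadjusted p under 0.05. The other calls were erythrocyte markers (0.77 ± 0.55), neutrophil markers (0.30 ± 0.18) and type 2 inflammation genes (0.37 ± 0.16) higher, and cholesterol synthesis genes (-0.15 ± 0.10) and dendritic cell markers (-0.24 ± 0.18) lower. Camera adjusted p was 0.00798, 0.0175, 0.0402, 0.000208 and 0.0402 in that order, and adjusted p = 0.557, 0.557, 0.507, 0.557 and 0.667 with an estimated correlation. On the 5 scan dates with both groups, the erythrocyte and type 2 lists were higher in SA on 3 and the neutrophil list on 2. The cholesterol synthesis list was lower on 3 and the dendritic cell list on 4. No member of these lists passed over all genes; adjusted over the list alone 1 cholesterol synthesis gene was lower. CCL18, a macrophage chemokine of the type 2 list, differed by 0.75 ± 0.43, and the neutrophil calprotectin subunits S100A8 and S100A9 by -0.02 ± 0.34 and 0.09 ± 0.28. Camera called 9 lists without the 7 arrays: neutrophil and dendritic cell markers no longer passed (adjusted p = 0.123 and 0.169), while ciliated (0.39 ± 0.36) and secretory epithelial markers (0.47 ± 0.32) and heat shock genes (0.11 ± 0.03) were called higher and type I interferon genes (-0.14 ± 0.12) lower. For these 4 camera adjusted p was 0.0188, 0.0188, 0.0432 and 0.0495, and adjusted p = 0.865, 0.864, 0.544 and 0.865 with an estimated correlation. Permutation of the list means gave adjusted p = 0.477, 0.425, 0.0411 and 0.477. On the 5 scan dates with both groups the ciliated list was higher in SA on 1 and the secretory list on 3.

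Over all arrays the remaining 25 lists did not pass between SA and control. Among leukocyte lists the mean difference was 0.21 ± 0.15 for eosinophil, 0.29 ± 0.17 for mast cell and basophil, 0.05 ± 0.25 for T cell, 0.12 ± 0.31 for cytotoxic and NK cell, -0.23 ± 0.22 for B and plasma cell, 0.19 ± 0.35 for alveolar macrophage and 0.12 ± 0.22 for monocyte and recruited macrophage markers. Epithelial lists differed by 0.18 ± 0.48 (ciliated), 0.30 ± 0.47 (secretory), 0.03 ± 0.30 (basal and squamous) and 0.04 ± 0.10 (alveolar type II). Type I interferon genes differed by -0.02 ± 0.20, interferon gamma genes by -0.10 ± 0.20, IL-17 and neutrophil chemoattractant genes by -0.02 ± 0.11, NF-kB early response genes by 0.00 ± 0.19 and heat shock genes by 0.10 ± 0.03, although IRF1 and GADD45B on the interferon gamma and heat shock lists rose. Asthma susceptibility locus genes differed by 0.00 ± 0.10, MHC class II by 0.01 ± 0.21, eicosanoid by 0.15 ± 0.10, matrix remodelling by 0.08 ± 0.14, LXR target by -0.03 ± 0.14, NRF2 antioxidant by 0.11 ± 0.07, proliferation by 0.11 ± 0.13, ribosomal protein by 0.03 ± 0.06 and mitochondrial respiratory chain genes by 0.01 ± 0.05. Of the fixed genes, the eosinophil gene CLC differed by 1.05 ± 0.45, the mast cell protease CPA3 by 0.90 ± 0.32, ALOX15 by 0.58 ± 0.53, IFNG by 0.54 ± 0.42, TSLP by 0.29 ± 0.33, IL33 by -0.05 ± 0.41 and SCGB1A1 by -1.55 ± 0.58, none passing (adjusted p = 0.490, 0.275, 0.922, 0.876, 0.944, 0.993 and 0.355); CPA3 passed without the 7 arrays (0.95, adjusted p = 0.0390).

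**Figure D2:**
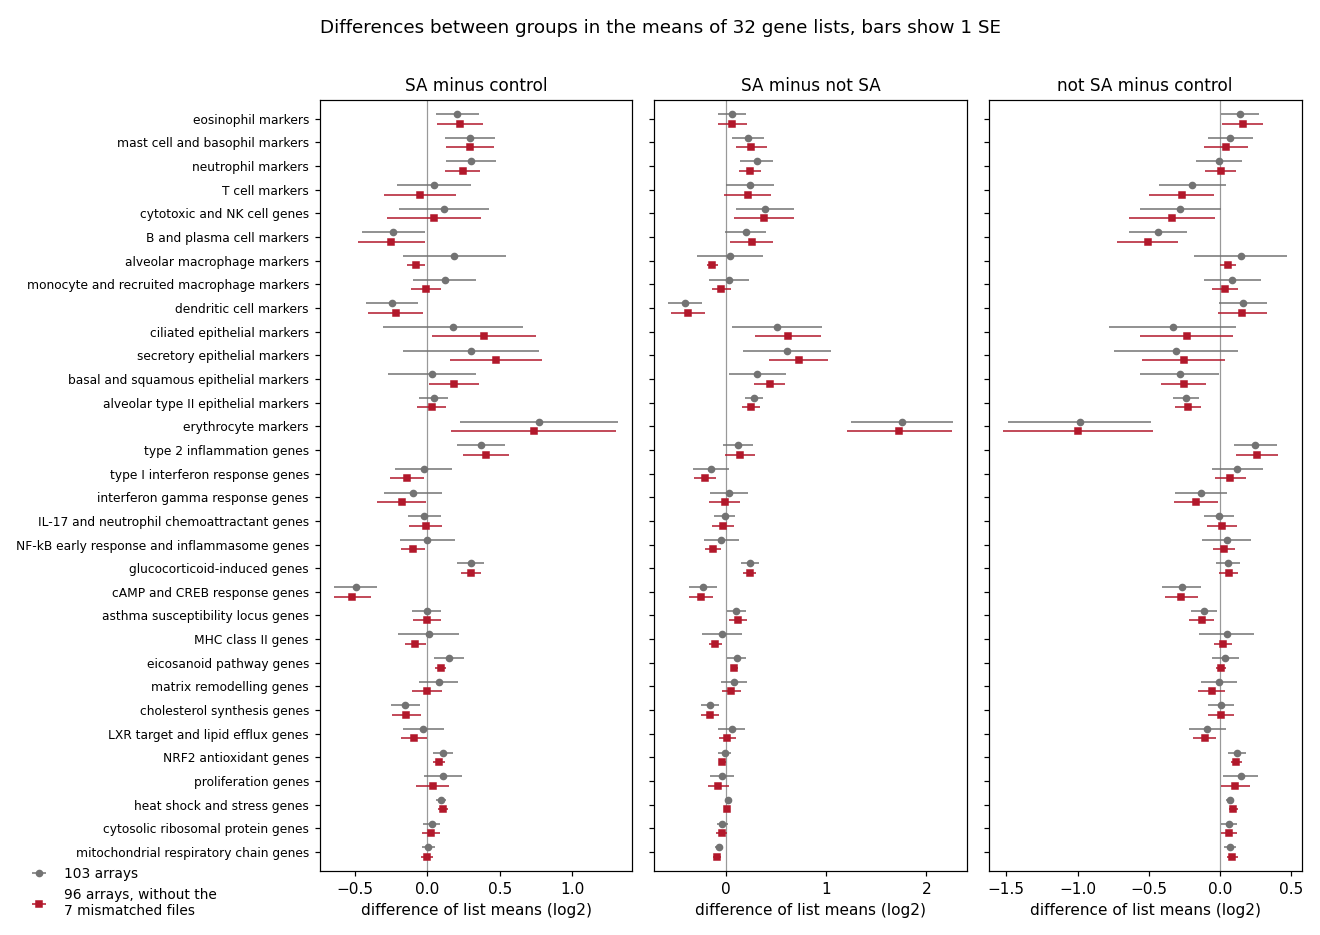
Difference of list means between groups (horizontal axis, log2) for the 32 lists in each of the 3 comparisons, with bars of 1 SE; grey circles show 103 arrays and red squares the 96 arrays without the 7 mismatched files. The cAMP and CREB list lies at -0.49 between SA and control, and the erythrocyte list at 1.75 between SA and not SA, and leaving out the 7 files shortened the bar of the alveolar macrophage list between SA and control from 0.35 to 0.06.

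SA samples were compared with not SA samples to ask what separates SA from not SA. SH3PXD2B rose 2.27-fold in SA over not SA (1.19 ± 0.21 SE, adjusted p = 0.00151, limma, n = 30 and 42), and TFPI, the inhibitor of the tissue factor pathway, rose 2.54-fold (1.34 ± 0.31, adjusted p = 0.0489), with another probe at 0.57. DDIT4, a stress and glucocorticoid-responsive inhibitor of mTOR signalling, rose by 0.81 ± 0.19 and GADD45B by 0.52 ± 0.12 (adjusted p = 0.0489 and 0.0368). GPAT3, an acyltransferase of triglyceride synthesis, fell by 0.81 ± 0.16 and the antiproliferative gene BTG3 fell by 0.69 ± 0.13 (adjusted p = 0.00991 and 0.00202). NFE2L2, which encodes the antioxidant regulator NRF2, fell by 0.31 ± 0.07 (adjusted p = 0.0235).

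In all, 18 genes passed between SA and not SA, 4 higher and 14 lower. The other named falls were small: the phosphatase PTP4A1 (-0.37), the ubiquitin ligases PJA1 (-0.32) and UBR3 (-0.28), the DNA primase subunit PRIM2 (-0.32), IRF2BP2 (-0.30), the splicing factor BCAS2 (-0.29), MCCC1 (-0.28), UFL1 (-0.26) and the kinase MAP2K4 (-0.25). Other probes of PTP4A1, PRIM2 and UBR3 lay as near 0 as -0.16, -0.05 and -0.09. FKBP5 (0.46 ± 0.18, adjusted p = 0.235), GSDMB (0.38 ± 0.20, adjusted p = 0.423) and ORMDL3 (0.19 ± 0.09, adjusted p = 0.396), the last 2 from an asthma susceptibility locus, did not pass over all arrays. They passed without the 7 mismatched arrays, at adjusted p = 0.0461, 0.0153 and 0.0161. CD3D (0.14 ± 0.23), FABP4 (-0.07 ± 0.40), SCGB1A1 (0.05 ± 0.54) and CLC (0.18 ± 0.42) did not pass over all arrays. Without the 7 arrays mean FABP4 was 2.88 in SA and 3.16 in not SA. Without the 7 arrays 1980 genes passed (459 higher, 1521 lower), among them all 18. With the scan date as a block DDIT4 alone passed without the 7 arrays (0.92, adjusted p = 0.0408; 1451 genes had an unadjusted p under 0.05), and none (0) over all arrays (limma; 486 at an unadjusted p under 0.05). SH3PXD2B and DDIT4 were higher in SA on all 6 scan dates that held both groups, TFPI on 5 and GADD45B on 4, and BTG3 was lower on 5. With the 7 left out, these dates held 16 of 28 SA and 33 of 40 not SA arrays. The genes were picked in the same arrays, so these counts are no independent test of scan date. Scaling by the median gave 8 genes higher and 160 lower, the authors' table gave 148, 66 higher and 82 lower, and leaving out the 1 SA sample with conflicting labels gave 4 genes, 1 higher and 3 lower.

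Erythrocyte markers were higher in SA than in not SA by a mean of 1.75 ± 0.51 (camera adjusted p = 4.49e-09; adjusted p = 0.138 with an estimated correlation; permutation adjusted p = 0.0482, and 0.0477 without the 7 arrays). None of its 9 measured members passed over all genes; adjusted over the list alone 7 were higher, such as the globins HBA2 (3.07 ± 0.86) and HBB (2.67 ± 0.81). The difference was 0.79 ± 0.63 with the scan date as a block and without the 7 arrays, and the list was higher in SA on 5 of the 6 dates. Glucocorticoid-induced genes were higher by 0.24 ± 0.09 (camera adjusted p = 0.00129; adjusted p = 0.179 with an estimated correlation; permutation adjusted p = 0.0643, and 0.0202 without the 7 arrays), with 2 of 18 members higher when adjusted over the list alone. Alveolar type II markers, the surfactant genes among them, were higher by 0.28 ± 0.09. Camera adjusted p was 0.00225, and 0.138 with an estimated correlation, and permutation adjusted p was 0.0482, and 0.0780 without the 7 arrays. SFTPC differed by 0.29 ± 0.18, with another probe at 0.88. Against control the list differed by 0.04 in SA and by -0.24 in not SA, so the difference lay mostly in lower values in not SA.

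Camera called 12 lists between SA and not SA, 9 higher and 3 lower, and none (0) with an estimated correlation (3 at an unadjusted p under 0.05). Markers of other airway cells were among them: ciliated (0.51 ± 0.45), secretory (0.61 ± 0.44) and basal and squamous epithelium (0.31 ± 0.28), with camera adjusted p = 0.00168, 0.00168 and 0.0163, and adjusted p = 0.677, 0.677 and 0.679 with an estimated correlation. These 3 lists differed by 1.79, 1.90 and 0.88 within the earlier scan round and by 0.15, 0.26 and 0.26 within the later, without the 7 arrays. Cytotoxic and NK cell genes (0.39 ± 0.29), T cell markers (0.24 ± 0.24) and neutrophil markers (0.31 ± 0.16) were higher, and dendritic cell markers (-0.40 ± 0.17), cholesterol synthesis genes (-0.16 ± 0.09) and mitochondrial respiratory chain genes (-0.07 ± 0.04) lower, with camera adjusted p between 0.00168 and 0.00903 and adjusted p = 0.677 with an estimated correlation for each. Of these members none passed over all genes; adjusted over the list alone 4 neutrophil genes were higher and 3 dendritic cell genes lower. Type 2 inflammation genes (0.12 ± 0.15), cAMP and CREB response genes (-0.23 ± 0.14), MHC class II genes (-0.04 ± 0.20) and alveolar macrophage markers (0.04 ± 0.33) were among the 20 lists that did not pass. Without the 7 arrays the alveolar macrophage list differed by -0.136 (permutation p = 0.0109, adjusted p = 0.078). Leaving out the 7 arrays gave 9 called lists: T cell, neutrophil and dendritic cell markers and cholesterol synthesis genes no longer passed (adjusted p = 0.133, 0.142, 0.0859 and 0.0571), and type I interferon genes were called lower (-0.21 ± 0.11, camera adjusted p = 0.00619; adjusted p = 0.687 with an estimated correlation).

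Not SA samples were compared with controls to ask which differences are present outside the severe group. CDC42EP3 rose by 0.52 ± 0.11 (SE, adjusted p = 0.0113, limma, n = 42 and 31). FOSL2 fell by 0.58 ± 0.15 and DUSP16, a phosphatase of MAP kinases, fell by 0.72 ± 0.19 (adjusted p = 0.0348 for both). The paraspeckle RNA NEAT1 fell by 0.60 ± 0.16 and the tubulin acetyltransferase ATAT1 fell by 0.65 ± 0.14 (adjusted p = 0.0357 and 0.0123).

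In all, 238 genes passed between not SA and control, 130 higher and 108 lower. The other named rises lay between 0.34 and 0.39: ZNF93, HRK, TRIM36, METTL18, CCDC112, ATP23, ST20-AS1, RIN2, TIPARP and B3GNT2. A further probe of HRK gave -0.31, and those of DUSP16, AVIL and SNX29P2 gave -0.28, -0.27 and -0.18. Other named falls were GUCY1B2 (-1.30), SFTA2 (-0.77), DNHD1 (-0.64), RDM1 (-0.63), AVIL (-0.62), LSMEM1 (-0.60), PGGHG (-0.60) and SNX29P2 (-0.59). GUCY1B2 was well above background on 19 control and 6 not SA arrays, and SFTA2 on 15 and 9; SFTA2 gave 0.02 after normexp background correction. SCGB1A1 differed by -1.60 ± 0.54 without passing (adjusted p = 0.0930), and by -1.62 without the 7 mismatched arrays (adjusted p = 0.00916). Without the 7 arrays 1671 genes passed (1147 higher, 524 lower), among them all 238. With the scan date as a block none (0) passed over all arrays (limma; 1942 at an unadjusted p under 0.05), and 575 without the 7 (379 higher, 196 lower), 179 of the 238 among them. On the 6 scan dates that held both groups FOSL2 and CREM were lower in not SA on 6 and NR4A2 on 4, and CDC42EP3 was higher on 5. With the 7 left out, these dates held 29 of 40 not SA and 26 of 28 control arrays. FOSL2 and CDC42EP3 were picked in the same arrays, and CREM and NR4A2 against the same controls. These counts are therefore no independent test of scan date. Scaling by the median gave 790 genes, 719 higher and 71 lower, and moving the sample with conflicting labels to not SA gave 116.

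Camera called 6 lists between not SA and control, 1 higher and 5 lower, and none (0) with an estimated correlation, where none (0) had an unadjusted p under 0.05 either. B and plasma cell markers (-0.43 ± 0.20), erythrocyte markers (-0.98 ± 0.50), cAMP and CREB response genes (-0.27 ± 0.14), basal and squamous epithelial markers (-0.28 ± 0.28) and cytotoxic and NK cell genes (-0.28 ± 0.28) were lower, and mitochondrial respiratory chain genes (0.07 ± 0.04) higher. Camera adjusted p was 0.0101, 0.0193, 0.0228, 0.0310, 0.0498 and 0.0193 in that order, and adjusted p = 0.978 with an estimated correlation for each. In the cAMP and CREB list FOSL2 fell, 1 other member rose and 16 of 18 did not pass; adjusted over the list alone 3 were lower and 1 higher. In the other 5 no member passed over all genes; adjusted over the list alone 1 mitochondrial gene was higher. Camera called 4 of these lists without the 7 arrays, as cytotoxic and NK cell genes and erythrocyte markers no longer passed (adjusted p = 0.0611 for both). The permutation of list means called none (0) of the 32 over all arrays (3 at an unadjusted p under 0.05). It called 2 without the 7 arrays, both higher, NRF2 antioxidant genes (0.12, adjusted p = 0.0320) and heat shock genes (0.09, adjusted p = 0.0451), and it also called heat shock genes between SA and control (0.11, adjusted p = 0.0411). Glucocorticoid-induced genes (0.06 ± 0.09), type 2 inflammation genes (0.25 ± 0.15), alveolar type II markers (-0.24 ± 0.09) and T cell markers (-0.19 ± 0.24) did not pass. For alveolar type II markers over all arrays the permutation p was 0.00667 (adjusted p = 0.213). With the 7 left out that list was lower in not SA on all 6 scan dates with both groups.

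The SA and not SA groups share their controls. Across genes, which are not independent replicates, the log2 differences from control in SA and in not SA correlated at r = 0.477 (bootstrap SD 0.182). With the controls split between the comparisons r was 0.0629 (SD 0.218 over the splits). Unchanged groups were simulated by shuffling the group labels over the deviations of all arrays from their group means. The shared controls of a draw thus came from any group, and the simulated r was 0.527 (SD 0.253). The covariance was 0.0185 against a simulated 0.0167 (SD 0.0154), a difference of 0.00179. Without the 7 arrays r was 0.390 against a simulated 0.512 (SD 0.167), and the covariance 0.0175 against a simulated 0.0105 (SD 0.00517), a difference of 0.00705. With the controls split, r was then 0.157 (SD 0.105 over the splits) and the covariance 0.00796. Both comparisons called 2 genes higher, CDC42EP3 among them, and 5 lower, AFMID, DUSP8, FOSL2, SCO2 and TP53INP2 (named after their values were seen); without the 7 arrays 35 higher and 77 lower were called in both. How many genes shared controls alone would put in both was not tested.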

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

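The tests without the 7 mismatched arrays, and those of dim hybridization, of the handling of the cells and of fewer macrophages, were chosen only after the result was seen. Probes that no gene name could be given to stood outside the comparisons of genes, and some of them differed from the controls: of 9512 such probes 73 passed between SA and control and 734 between not SA and control (limma), against 411 and 1850 without the 7 arrays. Between SA and not SA none (0) passed (808 at an unadjusted p under 0.05), and 377 without the 7 arrays.

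The 5 scanner files that match no column of the authors' table carried the genes of another tissue. The ciliated epithelial list had a median of 4.11 over the 5 arrays (log2, relative to the 75th percentile), above each of the other arrays, and the alveolar macrophage list a median of -1.09, below each of them. Dim hybridization is argued against, because 0 of the 5 arrays had a lower share of probes well above background than all others. A candidate explanation is that these files hold RNA of airway epithelium, which the labels' protocol describes as brushed in the same procedure.

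Erythrocyte genes were higher in SA than in not SA by 1.75 ± 0.51. Their members moved together over the arrays of both groups (median pairwise r 0.841), which is consistent with differing amounts of red blood cells in the lavage, and HBA2 and HBB differed by 3.07 and 2.67. With the scan date as a block, and without the 7 arrays, the difference went from 1.73 ± 0.53 to 0.787 ± 0.63, so scan date and group cannot be told apart here: the value lies between what a date effect and its absence would leave. A difference between the groups in bleeding stays open, untested.

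The cAMP and CREB response list was lower in SA than in control by -0.49 ± 0.15. Without the 7 arrays the alveolar macrophage list differed by -0.0778 ± 0.06, more than 2 SE short of the -0.258 that fewer macrophages as the cause would need, though not clear by 1 SE of the stricter bound set for ruling them out. A weaker early response to handling of the cells would lower the heat shock list, which was higher by 0.108 ± 0.03. That list holds GADD45B, itself called higher in SA (mean 2.79 against 2.16 in control without the 7 arrays), and was not tested without it. A weaker response would also lower the NF-kB early response list, which differed by -0.10 ± 0.09, the way handling needs. The bound for handling asked both lists to fall, and the bound against it asked neither to fall by more than 1 SE. Neither bound was met, so handling stays open as the whole cause or as part of it. The bounds for macrophages and for handling were chosen with the values known. Scan date cannot be told apart from group, because the difference went from -0.52 ± 0.13 to -0.343 ± 0.16 with the date as a block. A difference in treatment or disease between the groups stays open, untested.

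Random splits of the same arrays into groups of the same sizes, 100 per comparison with the real one included, tested whether chance can give as many genes. For SA against control 1 split, the real one, reached 56 genes (highest other 2), and for not SA against control 1 split reached 238 (highest other 1), so a random assignment of arrays can be excluded there. For SA against not SA 2 splits reached 18, the real one and another with 50. That share of 100 splits is under the 0.05 set beforehand, but it rests on few splits. Since 1 random split called more genes than the real one, chance is less firmly excluded here. Why that split gave 50 was not tested. Without the 7 arrays 1 split reached the real count in each comparison (426 against a highest other of 303, 1980 against 1, and 1671 against 1). The random splits take no account of scan date: with the date as a block 6, 0 and 0 genes passed over all arrays (limma; 1106, 486 and 1942 at an unadjusted p under 0.05), and 93, 1 and 575 without the 7 arrays, for SA against control, SA against not SA and not SA against control, so excluding chance does not exclude a part played by scan date. All 56, 18 and 238 called genes kept their sign with the block, but only 4, 0 and 0 stayed called over all arrays. They were picked for their differences in the same arrays, so a kept sign was likely beforehand and is little support. SH3PXD2B, 1 example, went from 1.18 to 0.95 between SA and control without the 7 arrays. How much of each lost call is due to scan date was not tested. For the number of lists called by camera chance cannot be excluded: 68 splits reached the 7 lists of SA against control (highest other 21), 25 reached the 12 of SA against not SA (highest other 19) and 79 reached the 6 of not SA against control (highest other 20). In each comparison all 99 other splits called at least 1 list, so a camera call at the preset correlation is weak evidence on its own.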

How the results depend on the processing

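Alternatives that leave out mismatched arrays or use 1 scan round, and the permutation of list means, were chosen only after the results were seen; the others were planned. Of the passing genes that the fixed rule picks, 24, 16 and 25 in SA against control, SA against not SA and not SA against control, 1 (SFTA2) changed sign over 27 alternatives, and 127 of 647, 170 of 432 and 162 of 673 values fell short of the threshold. Of 29 alternatives for lists, the cAMP and CREB call between SA and control held in 28 (from -0.53 to -0.33) and the glucocorticoid-induced call in 27 (from 0.23 to 0.38). The estimated list correlation ended both calls (adjusted p = 0.170 and 0.130), the permutation of list means ended the glucocorticoid-induced one (adjusted p = 0.0717), and all alternatives but these 2 keep the preset correlation of 0.01. At that setting camera also called at least 1 list in every random split of the arrays, so the held calls are weak support. The correlation of fold changes ranged from 0.378 to 0.757 over 27 alternatives. Dim probes limit the values: RPH3A, GUCY1B2 and SFTA2 were not well above background on most arrays of some group. The cause of the changes below was not tested, except where a reason is stated. A fit on 1 scan round holds fewer samples. Counts of genes are given for SA against control, SA against not SA and not SA against control in that order.

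Normexp correction gave 31, 9 and 65 genes and 3 lists between not SA and control, with SFTA2 at 0.0230, mitochondrial genes at -0.00693 there and 0.0266 between SA and not SA, and ribosomal genes at 0.0585 between SA and not SA. Median scaling gave 34, 1.7e+02 (8 higher, 160 lower) and 790 genes and 11 lists between not SA and control. It moves all genes of an array alike. The median difference over all genes was then -0.076 between SA and not SA and 0.098 between not SA and control. Array weights gave 313, 785 and 2676 genes. The authors' table gave 318, 148 and 394 genes and 0 lists between not SA and control (camera; 12 at an unadjusted p under 0.05), MHC class II genes at -0.134 between SA and control and alveolar macrophage markers at -0.0958 between SA and not SA. The scan date as a block gave 6, 0 and 0 genes (limma; 1106, 486 and 1942 at an unadjusted p under 0.05), 11 lists between SA and control and 10 between not SA and control, a correlation of 0.757, and ciliated markers at -0.433 between SA and control. The epithelial covariate gave 205, 129 and 431 genes and ciliated markers at -0.0381 between SA and not SA. The lymphocyte covariate gave 94 and 35 genes in the SA comparisons and T cell markers at -0.0457 between SA and not SA. Each covariate was itself the mean of the marker lists it stands for, the ciliated and the T cell list among them. With it in the model the differences of those lists together are held near 0. A changed sign of 1 such list is therefore no separate result. The estimated list correlation gave 0, 0 and 0 lists (camera; 3, 3 and 0 at an unadjusted p under 0.05), and the permutation of list means 1, 2 and 0 (4, 4 and 3 at an unadjusted p under 0.05).

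Between SA and not SA alone, 6 genes passed with no filter on dim probes, 29 with the filter at 52 arrays, 5 with the mean over probes, 6 with every probe on its own, 29 with a trend and robust variance, 5 with the slide as a random block, 5 with array brightness as a covariate and 4 without the sample with conflicting labels. The filter at 52 arrays gave 3 lists between not SA and control, and the mean over probes put SIK1 at -0.875 between SA and control. With only the 2 groups compared 6 genes passed between SA and not SA and 410 between not SA and control, and with the sample of conflicting labels moved to not SA 2 and 116.

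The replicate block, with the replicate number as a fixed factor, gave 27, 77 and 554 genes. Same-numbered arrays of different groups did not deviate together (mean r -0.0141 over 70 pairs, 23 of them over 0.1, against 0.0216 for other pairs), so the numbers do not pair the samples.

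Without the 5 arrays that match no column 403, 1514 and 1347 genes passed, and 2 lists between not SA and control. Without all 7 mismatched arrays 426, 1980 and 1671 passed. With the 7 left out, the scan date as a block gave 93, 1 and 575 genes and alveolar macrophage markers at -0.119 between SA and not SA, and the slide as a random block 350, 1504 and 1651 genes. The epithelial covariate then gave 450, 1229 and 1552 genes, 2 and 4 lists in the SA comparisons and ciliated markers at -0.142 between SA and not SA. That sign is no separate result either, because the covariate holds the ciliated list. Array brightness gave 441, 838 and 1603 genes, 4 lists between SA and control and alveolar macrophage markers at -0.166 between SA and not SA. The authors' table without 8 mismatched samples and with the date block gave 110, 1 and 229 genes (62 higher and 167 lower in the last), 5 lists between SA and not SA and 2 between not SA and control, and mitochondrial genes at 0.00806 between SA and not SA.

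The earlier scan round alone (9 control, 16 not SA and 7 SA arrays) gave 7, 0 and 109 genes (limma; 1667, 1978 and 2624 at an unadjusted p under 0.05) and 13 lists between SA and control. There T cell markers lay at -0.484, cytotoxic and NK cell genes at -0.452, basal and squamous markers at 0.650, type I interferon genes at 0.413, cholesterol genes at 0.0509 and proliferation genes at -0.257. Between SA and not SA it put cholesterol genes at 0.176, ribosomal genes at 0.131 and mitochondrial genes at 0.0437, and between not SA and control ribosomal genes at -0.117. The later round alone (19, 24 and 21 arrays) gave 210, 1005 and 59 genes.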

Other observations

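The values without the 7 mismatched arrays were looked at only after the full results were seen; the test of the relation within SA was written before that relation was computed. Secretory and macrophage genes named by the fixed rule showed differences in those 96 arrays that the full set did not call. The club cell genes SCGB1A1 and SCGB3A1 fell by 1.62 ± 0.43 and 1.65 ± 0.43 in not SA against control (adjusted p = 0.00916 and 0.00903, limma, n = 40 and 28), and differed by -1.56 in both with the scan date as a block (adjusted p = 0.0518 and 0.0567). In SA they differed from control by -1.45 and -1.37 (adjusted p = 0.0676 and 0.101), by 0.29 and 0.29 in the earlier scan round and by -2.12 and -2.00 in the later.

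PLAUR, the urokinase receptor, fell by 0.39 ± 0.09 in SA against control and by 0.30 ± 0.09 against not SA (adjusted p = 0.00816 and 0.0151), and IL1B fell by 0.41 ± 0.13 in SA against not SA (adjusted p = 0.0218). The keratins KRT18 and KRT19 rose by 0.80 ± 0.18 and 0.96 ± 0.34 in SA against not SA (adjusted p = 0.00215 and 0.0427). GSDMB fell by 0.47 ± 0.14 in not SA against control (adjusted p = 0.0179) and lay at -0.00 ± 0.15 between SA and control. With the scan date as a block none of these 4 genes, nor GSDMB, passed, with adjusted p from 0.0708 (PLAUR, SA against control) to 0.590 (KRT19). CEBPE, a granulocyte transcription factor, rose by 0.38 ± 0.09 in SA against control (adjusted p = 0.00562; 0.21 with the block, adjusted p = 0.442).

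A hypothesis was that glucocorticoid-induced genes go with lower cAMP and CREB response genes within SA. The values gave it no support: without the 7 arrays r was 0.197 in SA (n = 28, permutation p = 0.316), 0.251 in control (n = 28, p = 0.199) and -0.132 in not SA (n = 40, p = 0.415), none of them told from 0. The bound written beforehand against it, an r of 0 or higher in SA, was met, though not by more than its spread. The hypothesis was left open, not rejected, only after the value was seen. Over all 30 SA arrays r was 0.429 (permutation p = 0.0187), opposite in sign to the hypothesis, and 0.0512 without the 2 farthest samples.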
